A study of Mus musculus with 12 samples.

How the data were processed

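RNA from 12 samples of IMG cells was taken by spin column and made into libraries with a stranded mRNA kit from 2 ug of total RNA, per the labels' protocols. Reads were trimmed, per the file headers, and the build was mm10, per the submitters' processing notes. The aligner, the counter, their versions and whether strand was used in counting are not given in the sources used here. The authors deposited 2 tables of 41325 genes, each with the controls and 1 treatment. Each holds whole-number counts per gene, per the file headers. It also holds RPKM, scaled by gene length and depth, and TPM, which sums to 1000000 per library, both made by the authors. The columns named CPM in the deposited tables are a signal on a normalised library size, since they sum to between 861325 and 1142855, and they were not tested. The authors' deposited tables also give a signed fold change as a score, a log2 fold change, a p-value and an adjusted p-value, from a test that is not given in the sources used here. In the authors' deposited table, 4926 genes have an adjusted p under 0.05 for oAb and 5597 for fAb. The control counts were identical in both tables, so the counts of all 12 libraries are on 1 scale. Of the identifiers, 41297 are in GENCODE M21, which served for names, overlaps and sequences.

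Samples were grouped by their titles. Counts were tested in edgeR 4.0.16 under R 4.3.3, separately on the 8 libraries of each comparison. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and dispersions and the quasi-likelihood F test were fitted robustly, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Before the data were examined, 29 gene lists, the named-gene rule, the tests and the other settings to be tried were fixed. The lists of mitochondrially encoded transcripts and of replication-dependent histones were fixed as measures of RNA quality. Lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. In oAb against scramble 4 list calls held with an estimated correlation, in fAb against scramble 3 and in fAb against oAb 0. The test fry asks only whether a list's genes move one way on balance.

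The named genes of a comparison are the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 2 CPM and no overlap between the groups' libraries, leaving out predicted genes. To these come the 3 members with the smallest adjusted p of each list past camera, and 10 fixed genes. The rule's part for lists not past camera was left out because over 30 genes were named. Timm23, Gm10273 and Galnt2 were chosen after their values were seen. Some genes that the rule names are not reported. Where a group had no count, the fold is a bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with an exact 95% interval. Floors and intervals cover counting error only. Totals of 13638721 to 18124419 counts per library set the precision. Of 84 named genes annotated, 9 have exons that overlap another gene on the same strand, 25 on the other strand, and 13 share at least 20% of their 50-base words with other genes; their counts are uncertain.

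The library sets were found after the splits of the samples and the values were seen. An earlier look used Rpl27 and Gm10273 as if they were a gene and its copy, but they share no word, and the sets were then defined by a share above or below 50% at Timm23 in the pair Timm23 and Gm10273, with the same libraries in each. Before that, libraries numbered 1 and 2 were set against those numbered 3 and 4. Those fits are given with the other alternatives. No label gives a batch. No duplicated library was found, since every pair of libraries of a group differed by more than counting noise (chi-square per degree of freedom 2.97 to 143).

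The alternatives were DESeq2 size factors, upper quartile scaling, no filter, a mean of at least 2 CPM, DESeq2 1.42.0, limma voom, a replicate block, all 12 libraries in a fit, a 1.5-fold minimum, a threshold of 0.01, and leaving out each library. Agreement between effects was set beside 100 simulations of unchanged groups and 6 ways of splitting the controls. Alternatives for normalised values were not run because counts were deposited, and settings with the library sets or library numbers were added later.

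The tests were checked on simulated counts with 200 changed genes. In the simulation of oAb against scramble (10938 genes), edgeR recovered 29.9% of genes changed by 1.5-fold, 82.1% by 2-fold and 92.4% by 4-fold, with 5.56% of its calls false. For fAb against scramble (10969 genes) these were 25.4%, 76.1%, 97.0% and 3.65%, and for fAb against oAb (10807 genes) 76.1%, 86.6%, 97.0% and 4.42%. DESeq2's false share was 18.8%, 19.8% and 9.5% in the same simulations, above the threshold it was run at. The check that false calls stay low was first set for all tools, failed for DESeq2, and was then applied to edgeR alone. In each simulation the list with 30 changed genes was found and 0 of the random lists passed. Genes were drawn independently there, so this does not test list calls where the members move together. In the data the estimated correlation reached 0.931, for ribosomal proteins in fAb against scramble. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.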

Results

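Gene expression was measured by RNA sequencing in IMG cells, an immortalised line of mouse microglia, the resident macrophages of the brain. The cells were of the C57Bl6/J strain and of the same passage. They were exposed for 8 h to a scramble control or to 1 of 2 preparations of amyloid beta, the peptide that accumulates in Alzheimer's disease, called oAb and fAb in the labels. The design text pairs the word fibrillar with oAb and oligomeric with fAb, whereas the abbreviations would read the other way round, so the groups are called oAb and fAb here without deciding which is which. Each group held 4 libraries, 12 in all, and the series set out to describe how the cells respond to the peptide. The libraries held between 13638721 and 18124419 counts, and between 13449 and 13948 genes had at least 1 count. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Values are normalised CPM (counts scaled to library size) as mean ± SD, or log2 fold changes ± SE, with n = 4 libraries per group, and coordinates are mm10 positions as the files give them.

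The treated libraries separated from the controls along a principal component holding 81% of the variance. Scramble library 3 stood apart from the other controls, with correlations of 0.944 to 0.965 to them against 0.981 to 0.991 among the other 3. It gave 10.6% of its counts to ribosomal protein genes, against 6.37% to 6.73% in the other controls. The libraries also fell into 2 sets that crossed the groups, found only after the values were seen. Timm23 (chromosome 14, 32180162 to 32201898), which encodes a mitochondrial import channel protein, has a near-identical copy, Gm10273 (chromosome 10, 59395632 to 59396757), and 94.9% of the 50-base words of Gm10273 also lie in Timm23. A further gene, Gm10233, shares words with both, and its counts did not enter the shares given here. Scramble libraries 2, 3 and 4 and oAb libraries 1 and 2 had 94.6% to 98.3% of the counts of this pair at Timm23, and are called the Timm23 set here. Scramble library 1, oAb libraries 3 and 4 and all 4 fAb libraries had 17.5% to 38.5% there, and are called the Gm10273 set. The share of counts from mitochondrial genes was 4.18% to 4.94% in the controls and 2.73% to 3.37% in the treated libraries.

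**Figure D1:**
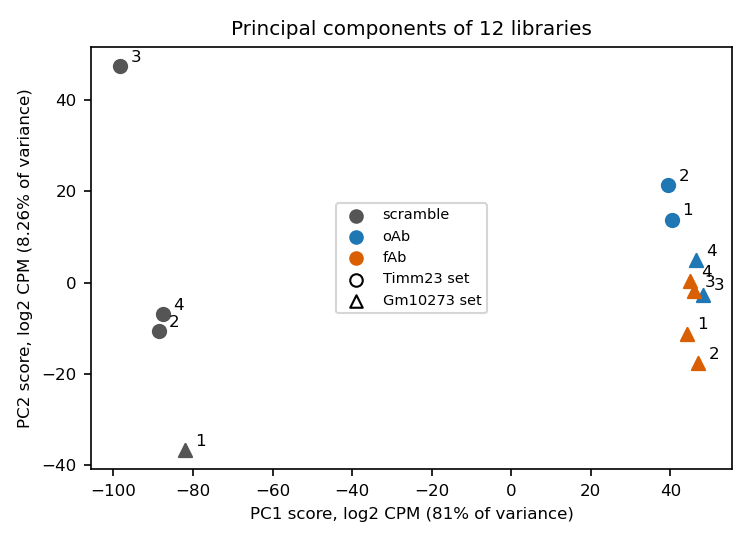
Scores of the 12 libraries on the first principal components of log2 CPM, coloured by group, with circles for the Timm23 set and triangles for the Gm10273 set and the replicate number beside each point. The horizontal axis holds 81% of the variance and parts controls from treated libraries, and the vertical axis holds 8.26%.

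**Figure D2:**
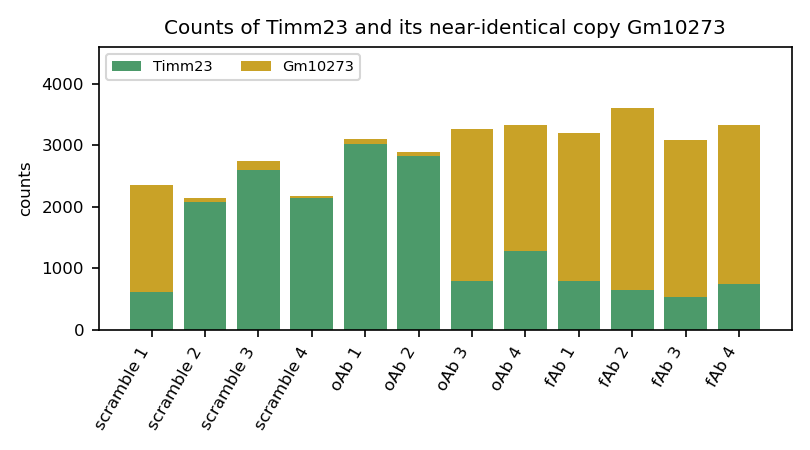
Counts of Timm23 and of its near-identical copy Gm10273 in each of the 12 libraries, stacked, with no error bars because each bar is 1 library. Between 94.6% and 98.3% of the pair's counts lie at Timm23 in 5 libraries and between 17.5% and 38.5% in the other 7.

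The comparison of oAb with scramble asks what this preparation changed after 8 h. Il1a, encoding the cytokine interleukin 1 alpha, went from 0.0131 ± 0.0262 to 525 ± 65.0 CPM, a ratio of 34550 with a 95% counting interval of 6200 to 1365000. Nos2, the inducible nitric oxide synthase, had a ratio of 18350 (3294 to 725000), and the complement factor gene Cfb a ratio of 10880 (1952 to 429700). The growth factor gene Csf3 and the chemokine gene Ccl12 had no count in any control and were at least 1898-fold and at least 1058-fold higher, with a floor of 3 counts over the control group. Il1b (chromosome 2, 129364570 to 129371139), encoding interleukin 1 beta, rose by 12.49 ± 0.27 on the log2 scale. The largest falls were in Cxcr4 (log2 fold change -6.89 ± 0.16), a chemokine receptor, Abca6 (-6.23 ± 0.56), a lipid transporter, the sphingosine 1-phosphate receptor gene S1pr1 (-5.53 ± 0.16), Gpr34 (-5.23 ± 0.44), Cmah (-5.19 ± 0.57) and the sialyltransferase gene St6gal1 (-5.04 ± 0.14). By the rule that chose these genes, all 4 oAb libraries lay on the same side of all 4 controls in each. The exons of Cfb overlap those of Gm20547 on the same strand over 79.5% of their length, so its counts are uncertain.

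All 40 measured genes of the type I interferon response rose, also 40 when adjusted over the list alone, with a median log2 fold change of 7.23 (camera adjusted p = 1.7e-30, or adjusted p = 0.00879 with an estimated correlation). They included Cxcl10 (8.53 ± 0.13), Cmpk2 (8.41 ± 0.13) and Oasl2 (7.89 ± 0.13). All 37 measured NF-kB targets, cytokines and chemokines also rose, 37 adjusted over the list alone, with a median of 4.38 (adjusted p = 2.09e-25, or 0.000394 with an estimated correlation). Ccl4 (5.90 ± 0.12), Ccl5 (11.30 ± 0.22) and Nos2 had the smallest adjusted p among them, and Tnf rose by 5.56 ± 0.16. These medians were the same with the genes absent from the controls set at their bounds. Among 23 ER chaperones and unfolded protein response genes, 18 rose and 0 fell, 19 and 0 adjusted over the list alone (median 0.96, adjusted p = 6e-07, or 0.00888 with an estimated correlation). Hspa5 was at 1.66 ± 0.10, Hyou1 2.82-fold higher and Dnajb9 at 1.82 ± 0.13. Of 18 heat shock genes, 14 rose and 0 fell, 14 and 0 adjusted over the list alone (median 0.80, adjusted p = 9.55e-05, or 0.0238 with an estimated correlation), among them Hsph1 (1.28 ± 0.08), Dnaja1 (1.07 ± 0.08) and Hsp90aa1 (1.02 ± 0.10), which shares 58.3% of its words with other genes.

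Stress and metabolic lists rose with calls that were lost with an estimated correlation. Of 36 genes of the integrated stress response, 25 rose and 1 fell, 26 and 2 adjusted over the list alone (median 0.97, adjusted p = 2.44e-07, or adjusted p = 0.113 with an estimated correlation). The cystine transporter gene Slc7a11 was at 5.98 ± 0.25, Cth at 3.17 ± 0.13 and Atf3 at 1.90 ± 0.09. Of 26 NRF2 targets, which serve antioxidant defence, 15 rose and 1 fell, 15 and 1 adjusted over the list alone (median 0.61, adjusted p = 0.000603, or adjusted p = 0.113 with an estimated correlation). Hmox1 was at 3.40 ± 0.11, Srxn1 at 2.79 ± 0.11 and Gsr at 2.10 ± 0.09. Glycolysis and hypoxia genes rose in 17 and fell in 3 of 29, 18 and 3 adjusted over the list alone (median 0.71, adjusted p = 9.48e-05, or adjusted p = 0.113 with an estimated correlation). P4ha1 was at 1.83 ± 0.08, Bnip3 at 2.07 ± 0.09 and the glucose transporter gene Slc2a1 at 2.22 ± 0.12. Cholesterol synthesis genes rose in 15 and fell in 0 of 24, 15 and 0 adjusted over the list alone (median 0.67, adjusted p = 0.000154, or adjusted p = 0.102 with an estimated correlation). Insig1 was 2.21-fold higher and Lss at 1.06 ± 0.11. Immediate early genes rose in 16 and fell in 5 of 28, 17 and 5 adjusted over the list alone (median 0.83, adjusted p = 0.00165, or adjusted p = 0.363 with an estimated correlation). Dusp1, a phosphatase gene, was at 3.29 ± 0.11 and Dusp5 at 3.84 ± 0.15.

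Receptor and activation lists moved in both directions. Of 28 amyloid binding and phagocytic receptors, 18 rose and 8 fell, 18 and 8 adjusted over the list alone (median 0.71, adjusted p = 0.0103, or adjusted p = 0.113 with an estimated correlation). The Fc receptor genes Fcgr1 (3.40 ± 0.11) and Fcgr2b (2.87 ± 0.14) and the scavenger receptor gene Msr1 (2.33 ± 0.12) rose. Trem2 (chromosome 17, 48346401 to 48354147), a lipid-sensing receptor linked to Alzheimer's disease risk, fell from 273 ± 85.7 to 69.9 ± 7.13 CPM (log2 fold change -1.96 ± 0.20, edgeR adjusted p = 3.29e-05). Of 13 genes of alternative activation, 9 rose and 3 fell, 9 and 3 adjusted over the list alone (median 1.21, adjusted p = 0.0103, or adjusted p = 0.113 with an estimated correlation). The list's top genes were Il1rn (6.71 ± 0.15), which encodes an antagonist of interleukin 1, the chemokine gene Ccl22 (9.21 ± 0.36) and Msr1. Arg1, its best known member, was at the floor of 3 counts in both groups. Of 14 homeostatic microglia genes, 11 fell and 2 rose, 11 and 2 adjusted over the list alone (median -1.33, adjusted p = 0.0103, or adjusted p = 0.113 with an estimated correlation). P2ry13 (-3.42 ± 0.21), a purinergic receptor, and Gpr34 fell, while Gpr84 (4.79 ± 0.22), a fatty acid receptor, and the fractalkine receptor gene Cx3cr1 (0.62 ± 0.13) rose. Cx3cr1 was at 0.37 within the Timm23 set, where it lost its call (adjusted p = 0.0927), and at 0.56 with the set as a term (0.00759).

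Of 34 G2 and mitosis genes, 33 fell and 0 rose, 34 and 0 adjusted over the list alone (median -1.22, adjusted p = 2.3e-12, or adjusted p = 0.0524 with an estimated correlation), among them Nusap1 (-2.17 ± 0.12), Nuf2 (-1.79 ± 0.11) and Kif2c (-1.63 ± 0.11). Of 34 S phase genes, 16 fell and 3 rose, 17 and 4 adjusted over the list alone (median -0.33, adjusted p = 0.0087, or adjusted p = 0.367 with an estimated correlation). Tk1 was at -2.04 ± 0.15, Lig1 at -1.13 ± 0.10 and Rfc4 at -1.20 ± 0.11. The respiratory chain list was lower, with 8 of 38 genes past the test and 0 adjusted over the list alone (median -0.33, adjusted p = 0.0386, or adjusted p = 0.720 with an estimated correlation). Ndufa6 (-0.79 ± 0.25) and Ndufv2 (-0.55 ± 0.18) were among the genes with its smallest adjusted p. Ndufv2 lost its call when any oAb library was left out (adjusted p = 0.0568 to 0.0665), and Ndufa6 without oAb library 3 (0.0745) or 4 (0.0696) and with the replicate block (0.0918). The list lost its call without scramble library 3 (median -0.10, adjusted p = 0.247), with the set as a term (median -0.28, 0.0575) and with fry (0.228). It also lost its call without oAb library 1 (median -0.34, 0.0704) or 2 (median -0.36, 0.0503), where the median did not shrink. Lists that did not pass the list test were the disease-associated microglia genes (15 higher and 7 lower of 29), the lysosome (11 and 13 of 40), autophagy and TFEB signalling (10 and 11 of 34), LXR targets (9 and 5 of 21), p53 targets (6 and 10 of 22), amyloid processing (7 and 3 of 13), ribosomal proteins (0 and 1 of 40), mitochondrially encoded transcripts (2 and 7 of 15) and histones (0 and 1 of 5). Some of these lie near the threshold. Amyloid processing passed in 6 of the 8 fits that left out a library (adjusted p = 0.00955 to 0.0421), mitochondrially encoded transcripts without scramble library 3 (0.0309) or oAb library 3 (0.0184) and with the set as a term (0.0379), and disease-associated microglia genes without scramble library 3 (0.0354). With fry these 3 lists passed (0.000201, 0.0113 and 0.0113), as did LXR targets (0.00137). Ribosomal proteins passed with the replicate block (0.0264) and without scramble library 1, 2 or 4 and within the Timm23 set (0.00968), but their median went from -0.29 to -0.04 without scramble library 3. They did not pass with fry (0.318) or with an estimated correlation (0.764).

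Among the genes fixed in advance, Tfeb, encoding a regulator of lysosomal genes, had a log2 fold change of -1.17 ± 0.36 (edgeR adjusted p = 0.0224) and Apoe, a lipid carrier, one of -1.19 ± 0.37 (0.0237). Both kept their direction in every setting. With the set as a term both passed, Tfeb at -0.92 (adjusted p = 0.00192) and Apoe at -1.01 (0.0187), and Tfeb passed within the Timm23 set (-0.94, 0.0153). Tfeb lost its call with the replicate block (-1.18, 0.0846) and without scramble library 3 (-0.99, 0.0741) or 4 (-1.09, 0.0593) or oAb library 3 (-0.95, 0.0521) or 4 (-1.06, 0.0667). Apoe lost its call with the block (-1.18, 0.0632), without scramble library 2 (-1.14, 0.0558) or oAb library 3 (-0.95, 0.0559) or 4 (-1.12, 0.0671), and within the Timm23 set (-0.91, 0.111). With only the libraries numbered 1 and 2, Tfeb was at -0.28 and Apoe at -0.58, neither past the test. App, the gene of the amyloid precursor protein, rose by 1.07 ± 0.10. The lysosomal genes Ctsd (0.04 ± 0.18, adjusted p = 0.851) and Lamp1 (-0.24 ± 0.11, adjusted p = 0.0888) did not pass the test, although Lamp1 did with upper quartile scaling (0.01) and with all 12 libraries (0.0341). Without scramble library 3, Ctsd had a log2 fold change of 0.25 and an adjusted p of 0.0303, and 34.4% of its exons overlap Gm49369.

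**Figure D3:**
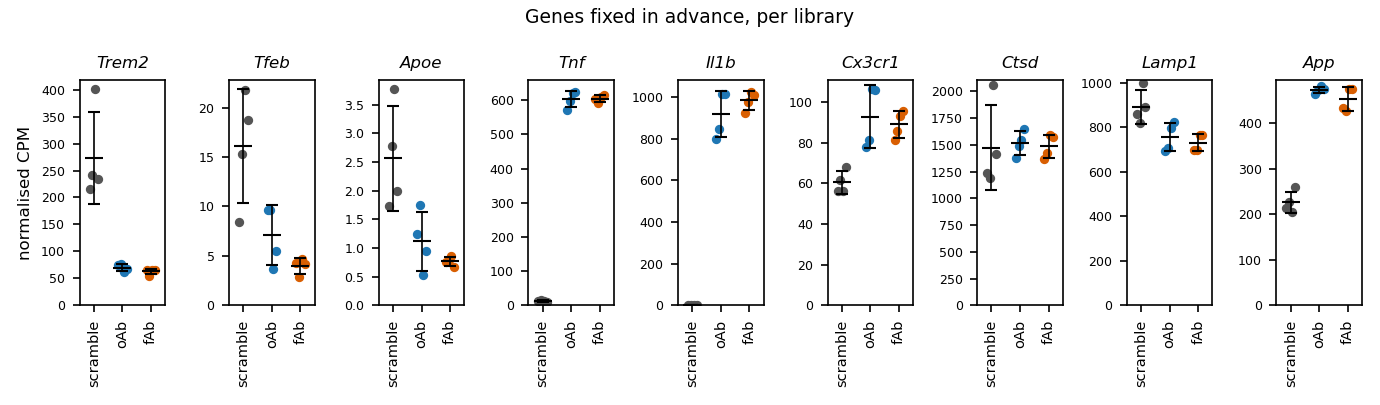
Normalised CPM of 9 genes fixed before the data were examined, for each library (points) of the scramble, oAb and fAb groups, with the mean and SD of 4 libraries as bars. Each panel has its own vertical axis starting at 0. Trem2 averaged 273 CPM in the controls, 69.9 in oAb and 62.9 in fAb.

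In all, 5761 of 11033 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2777 higher and 2984 lower. With upper quartile scaling the split was 2127 higher and 4015 lower, because that scaling moved the median of all genes to -0.24 from -0.07, and no named gene past the threshold changed direction. With the library set as a term 5734 genes passed, within the Timm23 set (2 oAb against 3 controls) 3792, and within the Gm10273 set (2 against 1, the lone control being assumed to vary like the other libraries) 7317.

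The comparison of fAb with scramble asks the same of the other preparation. Il1a rose to 556 ± 15.96 CPM, a ratio of 36480 (95% counting interval 6547 to 1441000), Nos2 had a ratio of 15690 (2815 to 619700) and Cfb one of 11130 (1997 to 439500). Csf3 and Ccl12, absent from every control, were at least 1653-fold and at least 1008-fold higher, and Il1b rose by 12.63 ± 0.23 on the log2 scale. The largest falls were in Cxcr4 (-6.90 ± 0.15), Abca6 (-5.78 ± 0.51), the transcription factor gene Sox4 (-5.15 ± 0.37), S1pr1 (-5.15 ± 0.15), Ypel3 (-5.03 ± 0.30) and Cmah (-4.94 ± 0.50). An antisense gene, Gm26735, overlaps 54.6% of the exons of Sox4.

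All 40 interferon response genes rose, 40 adjusted over the list alone (median 7.30, camera adjusted p = 1.84e-28, or 0.00245 with an estimated correlation), among them Oasl2 (7.89 ± 0.10), Gbp2 (10.46 ± 0.15) and Rtp4 (6.51 ± 0.10). All 37 NF-kB targets, cytokines and chemokines rose, 37 adjusted over the list alone (median 4.34, adjusted p = 2.53e-23, or 0.00126 with an estimated correlation). Ccl5 was at 11.06 ± 0.18, Ccl4 at 6.02 ± 0.10 and Tnf at 5.59 ± 0.15. Of 23 ER chaperones and unfolded protein response genes, 20 rose and 0 fell, 20 and 0 adjusted over the list alone (median 1.01, adjusted p = 9.14e-07, or 0.0208 with an estimated correlation), among them Hyou1 (1.58 ± 0.08), Hspa5 (1.74 ± 0.09) and Pdia4 (1.31 ± 0.08). These are the 3 lists whose call held with an estimated correlation.

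Of the other lists, the integrated stress response rose in 25 and fell in 4 of 36 genes, 25 and 4 adjusted over the list alone (adjusted p = 1.18e-06, or adjusted p = 0.111 with an estimated correlation). Slc7a11 was at 6.10 ± 0.22, Cth at 3.29 ± 0.13 and Atf3 at 1.93 ± 0.08. Heat shock genes rose in 13 and fell in 1 of 18, 14 and 1 adjusted over the list alone (adjusted p = 0.000282, or adjusted p = 0.103 with an estimated correlation). Hsph1 was at 1.26 ± 0.08, Hsp90aa1 at 1.09 ± 0.09 and Dnaja1 at 1.09 ± 0.09. Cholesterol synthesis genes rose in 16 and fell in 1 of 24, 16 and 1 adjusted over the list alone (adjusted p = 0.000384, or adjusted p = 0.111 with an estimated correlation). Insig1 was at 1.31 ± 0.10, Lss at 1.15 ± 0.10 and Nsdhl at 0.85 ± 0.08. Glycolysis and hypoxia genes rose in 17 and fell in 3 of 29, 17 and 3 adjusted over the list alone (adjusted p = 0.000605, or adjusted p = 0.198 with an estimated correlation). P4ha1 was at 1.79 ± 0.07, Bnip3 at 2.03 ± 0.09 and Pfkp at 1.31 ± 0.07. NRF2 targets rose in 14 and fell in 1 of 26, 14 and 1 adjusted over the list alone (adjusted p = 0.00075, or adjusted p = 0.141 with an estimated correlation). Hmox1 was at 3.36 ± 0.12, Srxn1 at 2.84 ± 0.10 and Gsr at 2.26 ± 0.08. Immediate early genes rose in 16 and fell in 4 of 28, 17 and 4 adjusted over the list alone (adjusted p = 0.0103, or adjusted p = 0.374 with an estimated correlation). Dusp1 was at 3.19 ± 0.11 and Dusp5 at 3.73 ± 0.15.

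Amyloid binding and phagocytic receptors rose in 17 and fell in 8 of 28, 17 and 8 adjusted over the list alone (adjusted p = 0.0103, or adjusted p = 0.0944 with an estimated correlation). Fcgr1 was at 3.37 ± 0.11, Fcgr2b at 3.05 ± 0.11 and Msr1 at 2.41 ± 0.11. Trem2 fell to 62.9 ± 5.26 CPM (-2.08 ± 0.20, edgeR adjusted p = 2.47e-05). Alternative activation genes rose in 9 and fell in 3 of 13, 9 and 3 adjusted over the list alone (adjusted p = 0.0202, or adjusted p = 0.141 with an estimated correlation). Il1rn was at 6.68 ± 0.13 and Ccl22 at 9.16 ± 0.30, and Arg1 was again at the floor. Amyloid processing and degradation genes rose in 8 and fell in 2 of 14, 8 and 2 adjusted over the list alone (adjusted p = 0.0334, or adjusted p = 0.278 with an estimated correlation). That list lost its call without scramble library 3 (adjusted p = 0.0852) and with the replicate block (0.052). The protease genes in it included Plau at 1.48 ± 0.08 and Mmp9 at 3.50 ± 0.26, and App was at 1.04 ± 0.10. Homeostatic microglia genes fell in 11 and rose in 2 of 14, 11 and 2 adjusted over the list alone (adjusted p = 0.00445, or adjusted p = 0.103 with an estimated correlation). Fcrls was at -2.27 ± 0.15 and Gpr34 at -4.86 ± 0.35, against rises in Gpr84 (4.61 ± 0.25) and Cx3cr1 (0.59 ± 0.10).

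G2 and mitosis genes fell in 33 of 34 and rose in 0, 33 and 0 adjusted over the list alone (median -1.23, adjusted p = 7.18e-12, or adjusted p = 0.0589 with an estimated correlation). Nusap1 was at -2.21 ± 0.11, Kif2c at -1.56 ± 0.10 and Aurkb at -1.46 ± 0.10. S phase genes fell in 19 and rose in 5 of 34, 19 and 5 adjusted over the list alone (adjusted p = 0.011, or adjusted p = 0.374 with an estimated correlation). Tk1 was at -1.95 ± 0.14 and Lig1 at -1.08 ± 0.10, while the replication licensing gene Cdc6 rose by 0.80 ± 0.09. Mitochondrially encoded transcripts fell in 10 and rose in 2 of 15, 11 and 2 adjusted over the list alone (median -0.43, adjusted p = 0.0194, or adjusted p = 0.141 with an estimated correlation). That list was fixed as a measure of RNA quality, and quality and treatment cannot be told apart here. Transcript mt-Cytb was at -0.90 ± 0.09, mt-Nd4 at -0.74 ± 0.10 and mt-Nd3 at -0.67 ± 0.09. Of mt-Nd3, 96.7% of the words also lie in other genes, and of mt-Nd4 62.4%.

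The respiratory chain list had 13 lower and 0 higher of 38 genes, 11 and 0 adjusted over the list alone (median -0.40, adjusted p = 0.0103, or adjusted p = 0.665 with an estimated correlation). The ribosomal protein list had 6 lower and 0 higher of 40 genes, 0 adjusted over the list alone (median -0.39, adjusted p = 0.0103, or adjusted p = 0.675 with an estimated correlation). With the set as a term in the fit of these 8 libraries their medians were -0.07 (adjusted p = 0.496) and -0.03 (adjusted p = 0.779), but in that fit the fAb effect rests on scramble library 1 alone. Ndufa6 (-1.17 ± 0.24), Ndufv2 (-0.72 ± 0.18), Cox5b (-1.26 ± 0.31), Rpl13 (-1.02 ± 0.31), Rpl27 (-1.47 ± 0.41) and Rplp1 (-1.23 ± 0.41) had their smallest adjusted p. None of these 6 passed in that fit, where Rpl27 (0.12) and Rplp1 (0.11) had the opposite sign. With the set as a term and all 12 libraries, Ndufa6 (-0.74, adjusted p = 0.0134) and Ndufv2 (-0.59, 0.0215) passed. Cox5b, Rpl13, Rpl27 (0.15) and Rplp1 (-0.22) did not. Without scramble library 3 the median of the ribosomal protein list went from -0.39 to -0.12 (adjusted p = 0.0777) and that of the respiratory chain from -0.40 to -0.17 (adjusted p = 0.0497). With fry neither list passed (0.224 and 0.177). Passing with fAb and not with oAb is not by itself a test of a difference between the preparations, which takes their direct comparison. Rplp1 lost its call without scramble library 3 or 4 and without fAb library 1, 2 or 3 (adjusted p = 0.0551 to 0.0891), and Rpl13 without fAb library 1 (0.0534) or 2 (0.0532). Other genes hold 57.8% of the words of Rplp1, 53.6% of Rpl27, 28.6% of Rpl13 and 25.6% of Cox5b, so their counts are uncertain. Disease-associated microglia genes (14 higher and 7 lower of 29), the lysosome (10 and 14 of 40), autophagy and TFEB signalling (11 and 11 of 34), LXR targets (10 and 6 of 21) and p53 targets (7 and 10 of 22) did not pass the list test. With fry, disease-associated microglia genes (0.014) and LXR targets (0.000115) passed.

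Tfeb had a log2 fold change of -1.97 ± 0.30 (edgeR adjusted p = 0.00043), and Apoe one of -1.69 ± 0.29 (0.000917). With the set as a term they were at -1.02 and -1.12 in the fit of 8 libraries, which rests on scramble library 1, and at -1.10 and -1.07 with all 12 libraries. Lamp1 (-0.25 ± 0.09, adjusted p = 0.0469) lost its call when scramble library 4 or any of the 4 fAb libraries was left out, with DESeq2 size factors (0.0619), with no filter (0.0761) and with the replicate block (0.0517). With the set as a term it had an adjusted p of 0.413 in the fit of 8 libraries, and of 0.0201 (log2 fold change -0.36) with all 12. Ctsd (0.05 ± 0.18, adjusted p = 0.836) had an adjusted p of 0.014 without scramble library 3.

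**Figure D4:**
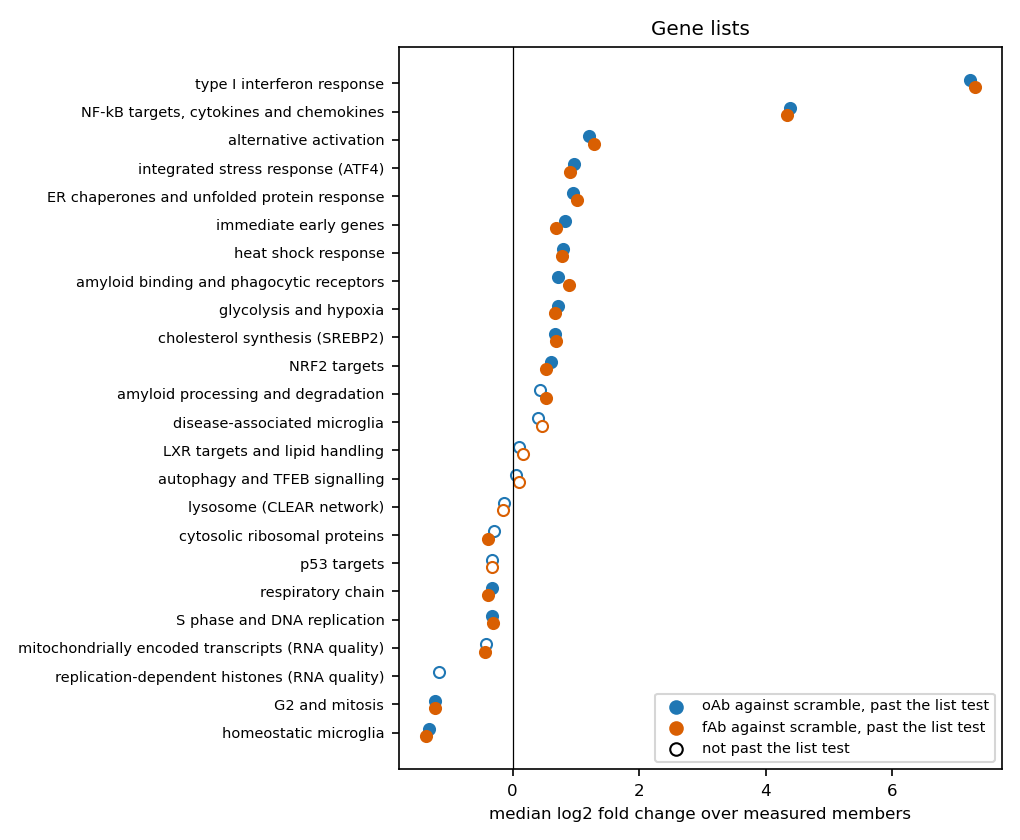
Median log2 fold change over the measured members of each gene list with at least 5 of them, for oAb (blue) and fAb (orange) against scramble, filled where the list passed the camera test. The interferon response stands highest, at 7.23 and 7.30.

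In all, 6235 of 11074 tested genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 3051 higher and 3184 lower, or 2273 higher and 4361 lower with upper quartile scaling, which moved the median of all genes to -0.225 from -0.04. With the library set as a term 3844 genes passed, where the fAb effect rests on scramble library 1 alone, and 5524 when all 12 libraries entered that fit. Within the Gm10273 set (4 fAb against 1 control, assumed to vary like the other libraries) 6506 passed, and the Timm23 set held no fAb library.

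The comparison of fAb with oAb tests the difference between the preparations itself. No gene of 10878 passed edgeR's test, 1391 had an unadjusted p under 0.05, limma voom also called 0 and DESeq2's Wald test called 16. Tnf differed by 0.00 ± 0.05 on the log2 scale, Il1b by 0.10 ± 0.08, Trem2 by -0.15 ± 0.08, Apoe by -0.53 ± 0.34 and Tfeb by -0.83 ± 0.31, none past the test. The 95% interval of the difference lay within 1.5-fold in both directions for 80.3% of the genes. The ribosomal protein list (median -0.11, camera adjusted p = 3.87e-06) and the respiratory chain list (median -0.09, 3.1e-05) were lower in fAb, although 0 of their genes passed over all genes and 2 of each adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.826 for each). No other list passed, the interferon response having a median of -0.06 (adjusted p = 0.142). It was lower in fAb and passed without oAb library 1 (0.00519) or 2 (0.0121) or fAb library 3 (0.0339), as did mitochondrially encoded transcripts without oAb library 1 (0.00519) or 2 (0.0265) and glycolysis and hypoxia genes without oAb library 3 (0.047) or fAb library 3 (0.0257) or 4 (0.0339). Immediate early genes (0.0315) and the integrated stress response (0.047) passed as lower in fAb without oAb library 3. An estimated correlation was not tried in the fits without a library. With all 8 libraries it gave an adjusted p of 0.826 for each of these lists. With the library set as a term and within the Gm10273 set (4 fAb against 2 oAb) 0 genes passed, and the Timm23 set held no fAb library. Trem2 was at -0.02 and -0.01 there, Apoe at 0.05 and 0.06 and Tfeb at -0.20 and -0.19. The lower values of these 3 genes in fAb given above may thus come from the library sets. In those fits, chosen after the result was seen, 7 and 11 lists passed. With the set as a term, the interferon response (median -0.14, adjusted p = 1.82e-07), mitochondrially encoded transcripts (-0.19, 4.14e-06) and the lysosome (-0.07, 0.00812) were also lower in fAb, and S phase genes (0.09, 0.00129) and p53 targets (0.14, 0.00917) higher. Within the set these 5 passed in the same directions. In both fits the difference rests on oAb libraries 3 and 4, the only oAb libraries in the set that holds all fAb libraries. The likeness of the 2 fits is thus no further support. An estimated correlation was not tried in those fits. With only the libraries numbered 1 and 2, 2573 genes passed, but there the 2 fAb libraries are all of the Gm10273 set and the 2 oAb libraries all of the Timm23 set, so set and group cannot be told apart.

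The oAb and fAb effects were close to each other. Across 10987 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.985 and a Spearman rho of 0.969. Both comparisons use the same 4 controls. Simulated unchanged groups against those controls gave a mean r of 0.497, and a mean covariance of 0.0366 against the 1.57 observed. In both comparisons 2644 genes were higher and 2712 lower, 762 and 863 being the overlap of independent lists, and 0 were opposite. With the controls split between the comparisons, r was between 0.895 and 0.958 and up to 26 genes were opposite. Nearly the same r, 0.985, came from a fit of all 12 libraries with the set as a term.

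**Figure D5:**
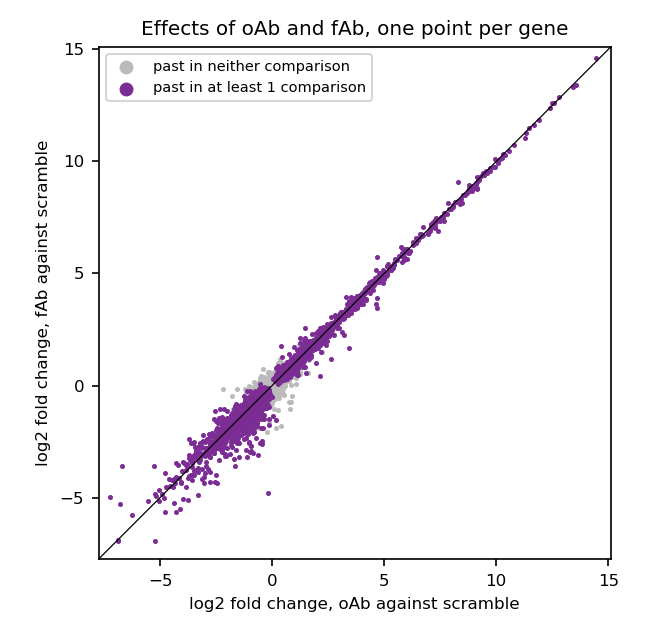
Log2 fold change of each gene in fAb against scramble (vertical axis) and in oAb against scramble (horizontal axis), with the line of equality. Purple points passed the test in at least 1 of the comparisons, and r across the 10987 genes is 0.985.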

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

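Among the tests in this part, those of admixture and of other cell types in scramble library 3, and those of length and GC content and of chance for the library sets, were chosen only after the result was seen. Of 333 groups of 4 libraries checked, 15 held a library far from the other 3, and 13 of the 15 are given here. At about 1 in 20, chance would give 16.6 of 333. That number is too high, since gene groups with very few counts could not stand out but were counted. Genes and lists are also not independent, so 15 against 16.6 is no test of chance. In scramble library 3 the share of counts in the top 20 genes was 13.8% (others 11.4% to 11.8%), that of ribosomal protein genes 10.6% (6.37% to 6.73%), Trem2 was at 400.7 CPM (216 to 241), Lig1 at 188 (149 to 155) and the S phase list at a mean log2 CPM of 6.29 (6.16 to 6.17). Scramble library 1 was low for the immediate early genes (mean log2 CPM 2.81, others 3.30 to 3.35) and for Cxcl10 (2.26 CPM, others 2.73 to 2.83). Among treated libraries, oAb library 4 was high for Nos2 (301 CPM), fAb library 2 was low for Trem2 (55.1) and high for Hsph1 (584), fAb library 4 was low for Dnajb9 (40.9), fAb library 1 was low for Fcrls (2.55) and fAb library 3 was high for Rpl27 (32.8). The respiratory chain list (median -0.0933) and the ribosomal protein list (median -0.112) were lower in fAb than in oAb in the direct camera test, and both calls were lost with an estimated correlation (adjusted p = 0.826 for each) and with fry (0.115 and 0.462).

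Splits of the 8 libraries of each comparison into 4 and 4 were counted. For oAb against scramble, 1 of 35 splits, the real one, gave 5761 genes, and the highest other gave 0. For fAb against scramble, 1 of 35 splits, the real one, gave 6235, and the highest other gave 0. Both argue against a chance assignment of these libraries. Chance is not excluded, since 1 of 35 is the smallest share that these splits can give. Chance differences between cultures are not covered, since the replicates may be technical. For fAb against oAb the real split gave 0 genes, which all 35 splits must reach, so that count says nothing about chance. The highest other there, 425 genes, set libraries 1 and 2 of both groups against 3 and 4, and points to a structure of the samples other than the groups.

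The libraries fall into 2 sets that cross the groups. In a fit of 11208 genes over all 12 libraries with the group as a term, 349 genes were lower and 10 higher in the Gm10273 set; Galnt2, 93.6% of whose words lie in other genes, mainly Gm20388, had 197 to 557 counts in the Timm23 set and 0 to 23 in the other. Shared reads are argued against as the whole source, since 7% of the genes that differ have at least 50% of their words in another gene. The share among the other genes was lower, 3.76%, so shared reads may be part of it. Chance stays open: 695 genes had values that did not overlap between the sets and the highest of the other splits of that shape (24 in all) gave 117, but the sets were chosen from these same values, so this is no test of it. Length and GC content took up 28.8% of the variance of the difference between sets, between the bounds set for and against it, so such a bias may be part of it and cannot be told apart from others (median GC content was 58.3% in the lower genes and 49% in other tested genes). A difference between library or processing batches stays open and untested, as the labels give none; in the deposited column names the Timm23 set is numbered 2 to 6 and the Gm10273 set 1 and 7 to 12, and no biological explanation was tested.

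Scramble library 3 stands apart from the other controls. Length and GC content took up 47.9% of the variance of its difference from the mean of the other 3, under the 50% set for it and above the 20% set against it, so this cannot be told apart from other causes. Admixture of treated material is argued against: the NF-kB list had a median difference of 0.114 (95% interval -0.144 to 0.289) and the interferon list -0.07 (-0.383 to 0.066), far under the 0.5 it would need. Cells of another type are argued against, since no marker list was above 1.04 times its highest level in the other controls. These levels are CPM without TMM scaling, with Aldoc, Mbp, Flt1, Map2 and Cd4 the highest genes of the 5 lists. The design gives no biological difference within the controls, and none was tested.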

How the results depend on the processing

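The tests with the library set as a term or within a set, those on library numbers, and leaving out libraries for the correlation were chosen only after the result was seen; the others were set in advance. Under the settings set in advance, no named gene or list past the threshold changed direction. The count for oAb was 4962 to 7174 without each library in turn, 3792 within the Timm23 set, 6479 with numbers 1 and 2 only and 3441 with numbers 3 and 4 only. The count for fAb was 5517 to 7598 without each library, 3844 with the set as a term, 6532 with numbers 1 and 2 only and 3337 with numbers 3 and 4 only. The fit giving 3844 rests on scramble library 1 as the only control beside fAb in its set. Fewer samples alone do not account for 3441 and 3337, since the fits on numbers 1 and 2 are of the same size. Scramble library 3, which stands apart from the other controls, is 1 of the 2 controls in the fits on numbers 3 and 4. Leaving it out of the full fits raised the counts, as given below. Whether it accounts for the low counts was not tested. With numbers 1 and 2 against 3 and 4 as a term the counts were 5810 for oAb, 6703 for fAb and 0 for fAb against oAb (smallest adjusted p = 0.053). Without scramble library 3 the counts were 7174 and 7598. The count for fAb against oAb was 0 without each library in turn and 16 with DESeq2. In the simulation of this comparison, with 200 changed genes, DESeq2 made 19 false calls among 200. The cutoff is looser there than where few genes change, so this does not give the false share of the 16. All 16 may be false. The count was 2573 with numbers 1 and 2 only, where set and group coincide. It was 3 with numbers 3 and 4 only (Gbp2, Cd300ld5 and Gm20479, named after their values were seen). The cause of these changes was not tested.

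Of the lists past the threshold, oAb had 15 and 4 with an estimated correlation (15 to 17 without each library), and fAb 18 and 3 (16 to 19). For fAb against oAb 2 lists passed, 0 with an estimated correlation, 0 with fry, 7 with the set as a term, 11 within the Gm10273 set and 2 to 5 without each library (4 without oAb library 1, oAb library 2 or fAb library 3, 5 without oAb library 3); the cause was not tested. The median of amyloid processing in fAb against oAb was -0.0649 within the Gm10273 set, where the list test gave lower (adjusted p = 0.0349), against higher and not past the threshold in the fit as reported. In fAb against scramble, Rpl27 turned to 0.115 with the set as a term, 0.153 with all 12 libraries as well and 0.122 within the Gm10273 set, and Rplp1 to 0.110 and 0.118 with the set as a term and within that set (-0.216 with all 12 libraries); the fits of 8 libraries and within the set rest on 1 control, and the cause was not tested.

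The correlation of effects was 0.976 to 0.987 without each library, 0.989 over genes past the threshold in either comparison, and 0.895, 0.958, 0.944, 0.951, 0.907 and 0.958 with the controls split, which leaves fewer controls per comparison; the cause was not tested. Replicate numbers gave no clear pairing of the samples. Deviations of same-numbered libraries correlated at -0.25 to 0.076 for oAb and scramble and at 0.088 to 0.198 for fAb and scramble. For fAb and oAb they correlated at -0.231 to 0.242. In these comparisons 0, 1 and 2 of 4 libraries correlated best with their own number. A weak pairing of fAb and scramble is not excluded. With the replicate block the counts were 5081 for oAb, 6292 for fAb and 0 for fAb against oAb. Depth limits genes near the floor, such as Arg1. In simulation, fewer than 30% of 1.5-fold changes against scramble were recovered (29.9% for oAb and 25.4% for fAb). Those simulations gave 144 and 137 edgeR calls, against 5761 and 6235 in the real fits. The Benjamini-Hochberg cutoff is stricter where fewer genes change, so these shares do not give the recovery in the real fits. Alternatives for normalised values or recovered reads were not run, since the files hold counts.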

Other observations

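Of the tests in this part, those of shared controls and of a ligand common to both preparations were chosen only after the result was seen. Markers of other brain and blood cell types, fixed as lists, had too few tested members for a list test. Endothelial and fibroblast markers summed to 9.9 to 16 CPM in the controls and 24.1 to 32.4 CPM in the treated libraries, and 3 of their 4 tested genes rose and 1 fell with oAb and with fAb. Of 2 tested neuron markers, 1 rose with oAb and 2 with fAb. Of 2 tested astrocyte markers 1 rose and 0 fell with each preparation, and of 2 tested oligodendrocyte markers 1 rose and 1 fell with oAb and 0 rose and 1 fell with fAb. Neuron markers summed to 1.47 to 5.58 and 11 to 14.7 CPM, oligodendrocyte markers to 127 to 172 and 73 to 80 CPM, and astrocyte markers to 117 to 128 and 85.4 to 99.8 CPM. Lymphocyte, neutrophil and dendritic cell markers summed to at most 1.41 CPM. The highest genes were Aldoc (102 CPM), Mbp (71.5), Flt1 (13.9), Map2 (8.06) and Cd4 (0.176), as means over the 12 libraries. Of 3 histone genes tested with fAb, 2 fell, and in fAb against oAb no gene of these lists passed.

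The oAb and fAb effects are alike. Shared controls are argued against as the whole source, since the covariance of the effects was 1.5732 and the highest of 100 simulations of unchanged groups 0.0392, and low precision is argued against, since 80.3% of genes have a 95% interval of the difference within 1.5-fold. A pattern-recognition ligand such as endotoxin carried by both preparations may be a common source, but no value here tests it. The NF-kB and interferon list means lay above the highest control in 16 of 16 cases, that is 2 lists in 8 treated libraries, which is the rise that prompted the idea and counts neither for nor against it. A response to amyloid itself predicts the same, no sample was treated with a ligand alone, and the explanations cannot be told apart with these libraries. A response common to both forms of amyloid stays open, as a hypothesis.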
